A study of Mus musculus with 27 samples.

How the data were processed

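Messenger RNA was measured in 27 samples of BALB/c mouse T cells, 3 in each of 9 groups: thymic Treg precursors, Foxp3+ and Foxp3- CD4 single-positive thymocytes at high, intermediate and low CD24, and Tregs and naive T cells from lymph node. Per the labels, RNA was extracted with RNeasy columns, and 50 ng was labelled with biotin for Affymetrix 3' expression arrays. The deposited values are intensities that the authors made with RMA, a method that corrects background, normalises between arrays and summarises probes into probe sets. The labels give no version or settings of RMA and do not say whether the arrays were processed together. Values were positive, from 3.55 to 24083, with array medians of 30.3 to 32.0, and so were taken as linear and transformed to log2 without an added constant. Image files and detection calls were not analysed here. The number of arrays limits the precision. The typical standard error of a log2 difference was 0.15 between groups of 3, 0.08 for the averaged comparison and 0.21 for an interaction.

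The table held 45101 probe sets. The platform's gene table gave a single gene symbol for 34958, several for 932 and none for 9211, and probe sets of the last 2 kinds were left out because they cannot be assigned to a gene. Each gene was represented by the single-symbol probe set with the highest mean over the 27 arrays, which gave 18194 genes, of which 9012 had several probe sets. Symbols were checked against the RefSeq annotation of GRCm38.p6, used for names alone, and 0 were changed. No gene was removed for low intensity.

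Groups came from the sample labels and series design. The Foxp3- groups were taken as conventional cells, as the design states, although their source labels carry the word Treg. Replicates were numbered by the leading digit of the description codes. Deviations from the group means were correlated across genes between same-numbered arrays, and numbers were taken to pair the samples of a comparison where every same-numbered pair was above 0.1. They did so in 14 of 17 comparisons, from the data alone, since no label states what the digit marks. The exceptions were the averaged comparison (lowest r = 0.02), Foxp3+ against Foxp3- at CD24int (0.02) and the difference between lymph node and thymus (0.07). Comparisons were fitted without a block, and a fit with one was an alternative.

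Comparisons used limma 3.58.1 in R 4.3.3, with a linear model of 9 group means on all 27 arrays and empirical Bayes moderation (prior degrees of freedom 5.98). P-values are two-sided and were adjusted by Benjamini-Hochberg over the 18194 genes within each comparison, and a gene passed at an adjusted p under 0.05. The 17 comparisons were Foxp3+ against Foxp3- thymocytes averaged over CD24 and at each CD24 level, lymph node Tregs against naive cells, each pair of CD24 levels within Foxp3+ and within Foxp3- cells, and the interaction of Foxp3 class with maturation. They also set precursors against Foxp3- CD24hi cells, Foxp3+ CD24hi cells against precursors, lymph node Tregs and naive cells against the CD24lo thymocytes of their class, and the difference between those last comparisons. These comparisons, the lists, the naming rule and the first set of alternatives were chosen before the data were examined.

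The naming rule took Foxp3, Il2ra and Cd24a in every comparison as a check of the sort. It also took the 8 largest rises and 8 largest falls among passing genes whose arrays did not overlap between groups, which chance gives in 10% of genes for 3 against 3. For averaged and interaction comparisons passing was enough. From each described list up to 4 were eligible, the passing with the smallest p and the failing member with the highest mean. Of passing named genes, 0 had another probe set passing oppositely, but some barely moved (averaged Plagl1 5.97 against 0.62 and 0.89).

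Lists of Treg signature, T cell receptor induced, NF-kB and TNF receptor, IL-2 and STAT5 target, immature thymocyte, mature thymocyte and egress, interferon response, DNA methylation and demethylation, cell cycle, effector Treg and trafficking, naive T cell, apoptosis, cytokine and helper lineage, and dissociation stress genes were written from general knowledge. So were marker lists of double-positive thymocytes, CD8 T cells, B cells, antigen-presenting cells, thymic epithelium, NK and NKT cells, and erythroid cells. Each was tested with camera in limma, with a preset correlation of 0.01 and also an estimated one, adjusted over the 21 lists within a comparison. Members were counted as passing over all genes and adjusted over the list alone. Lists of natural killer cell, innate-like T cell, liver, skeletal muscle, pancreas, brain and kidney genes were written after the values were seen. Lymph node signature genes were those that passed between lymph node Tregs and naive cells with at least a 2-fold change. Pearson correlations of fold changes across genes were computed between comparisons without arrays in common and carry no p.

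The alternatives were quantile normalization, removal of genes whose highest group mean was at or under an intensity of 31.0 (the median of all values), the mean of all probe sets of a gene, an intensity trend with robust hyperparameters, a fit of the compared groups alone, the replicate block, a minimum change of 2-fold, and each array left out in turn. Others were Foxp3- CD24int as reference for precursors, Foxp3+ CD24int in place of CD24hi against precursors, the estimated correlation, and a signature without the 2-fold minimum. Chosen after the values were seen were the averaged comparison without CD24lo groups, and CD24int in place of CD24lo for both interactions and for lymph node naive cells. Counts of changed genes were also taken over other splits of the same arrays, all 10 for 3 against 3 and 100 drawn with a fixed seed for the averaged and interaction comparisons.

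In simulated data the averaged comparison recovered 98.5% of 2-fold changes, 3 against 3 arrays 97% and an interaction 73.1% (11 of 143 calls false). Camera called the shifted list and 0 of 20 others at CD24hi, too few to rate false list calls. Tables and plots used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9.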

Results

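Messenger RNA was measured on 27 Affymetrix 3' arrays from BALB/c mice, 3 for each of 9 sorted T cell groups. CD4 single-positive thymocytes had been sorted by Foxp3, the transcription factor that defines regulatory T cells (Tregs), and by CD24, a surface protein that declines as thymocytes mature. This gave Foxp3+ and Foxp3- cells at high, intermediate and low CD24 (CD24hi, CD24int, CD24lo). The other groups were thymic Treg precursors, which the series title describes as Foxp3- CD25+, and Tregs and naive T cells from lymph node. CD24 group labels read Treg with Foxp3+GFP+ or Foxp3-GFP-, so GFP presumably marked Foxp3. The Foxp3- groups were still compared as conventional cells, as in the design. No label gave the CD24 level of the precursors.

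Intensities ran from 3.55 to 24083, array medians from 30.3 to 32.0, and the correlation between replicates of a group from 0.986 to 0.996. The number of arrays limits the precision, and no detection calls were analysed here, so fold changes of genes near the floor are compressed. Differences are log2 values, the first named group minus the second, ± the standard error from limma, with n = 3 arrays per group unless another n is given. Genes that rose or fell had an adjusted p under 0.05 among 18194 genes, and the largest changes named for 2 groups are among such genes whose arrays did not overlap between the groups. The labels do not say whether replicates came from separate animals, so p-values measure the spread between these samples. In a principal component analysis the leading components held 32.1% and 18.9% of the variance.

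**Figure D1:**
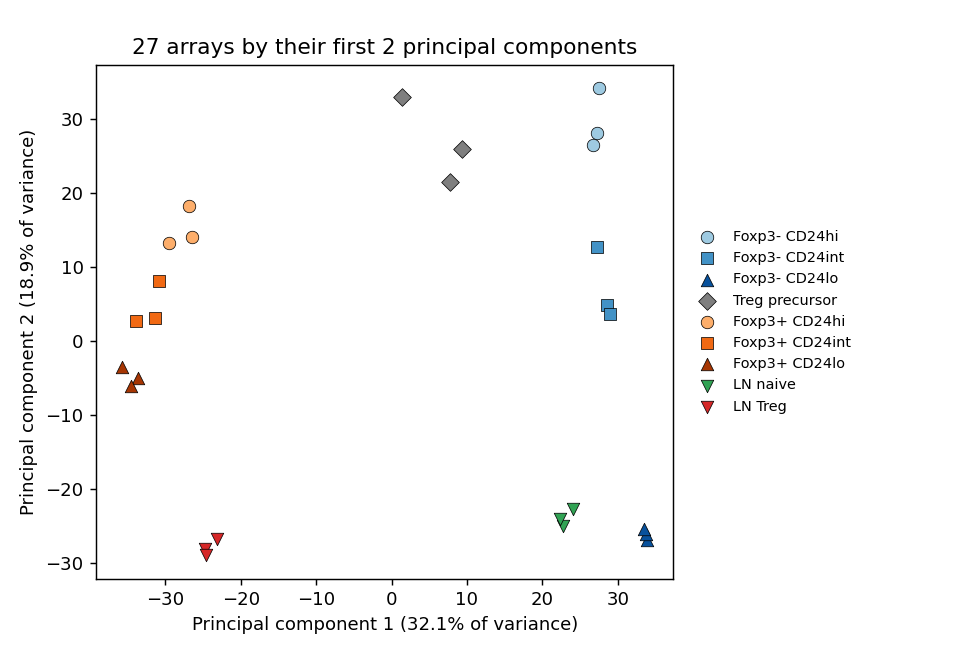
Scores of the 27 arrays on the leading principal components of the log2 intensities, which held 32.1% and 18.9% of the variance. Each point is an array and each of the 9 groups has 3.

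Genes behind the sort followed the labels. Foxp3 stood at 10.07 ± 0.11 log2 units (SD, n = 3) in Foxp3+ CD24hi cells, at 9.90 ± 0.15 in lymph node Tregs, at 3.97 ± 0.17 in precursors and at 3.80 ± 0.44 in Foxp3- CD24hi cells. Il2ra, which encodes CD25, was at 8.16 ± 0.29 in precursors, between 4.42 ± 0.23 in Foxp3- CD24hi and 10.18 ± 0.22 in Foxp3+ CD24hi cells. Cd24a declined along the CD24 gates, from 10.34 ± 0.50 to 9.08 ± 0.55 and 7.63 ± 0.40 in Foxp3+ cells and from 10.93 ± 0.24 to 8.21 ± 0.71 and 6.00 ± 0.82 in Foxp3- cells. It was highest in precursors, at 11.74 ± 0.43.

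**Figure D2:**
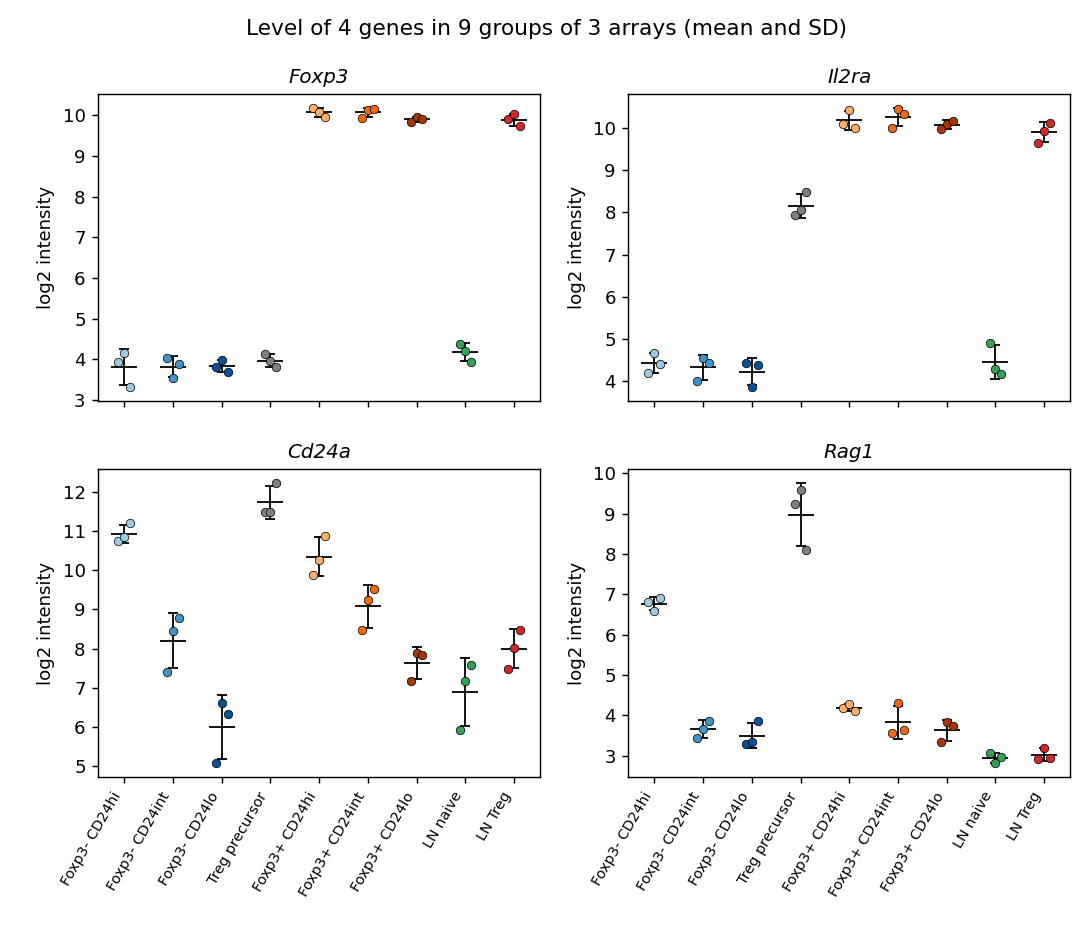
Log2 intensity of Foxp3, Il2ra, Cd24a and Rag1 in each array, with the mean and SD of each group (n = 3). Foxp3 was near 10.07 in Foxp3+ CD24hi cells and near 3.80 in Foxp3- CD24hi cells, while Cd24a was highest in precursors, at 11.74.

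Some differences between arrays did not follow the groups. Replicate 3 of Foxp3- CD24hi held liver transcripts, of which these examples were chosen after their values were seen: Alb stood at 11.65 against 3.49 to 4.23 in the 26 other arrays and Hpx at 9.97 against 3.39 to 3.98. Cell cycle genes stood 0.49 log2 units above the group mean in replicate 1, where 9 of 9 groups were above it, and at -0.31 and -0.18 in replicates 2 and 3. Among same-numbered arrays of different groups, deviations from the group means correlated above 0.1 in 103 of 108 pairs (median r = 0.36 across genes, which are not independent replicates), against a median of -0.17 for other pairs. Counts with the replicate number as a block are given where they differ by more than 1.5 times.

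The averaged comparison of Foxp3+ with Foxp3- cells had 9 arrays a side. Same-numbered arrays deviated together, so the 9 are not independent and p may be too low. Foxp3 was 73.5-fold higher (6.20 ± 0.10, adjusted p = 3.88e-24) and Il2ra 57.7-fold higher (5.85 ± 0.12, adjusted p = 4.93e-22). The other largest rises were in Plagl1 (5.97 ± 0.13), Itgb8 (5.48 ± 0.10), Penk (5.04 ± 0.14), Socs2 (4.98 ± 0.13), Cd83 (4.94 ± 0.11) and Dusp4 (4.70 ± 0.19), with adjusted p of at most 3.83e-16. The phosphodiesterase gene Pde3b fell most (-3.87 ± 0.20, adjusted p = 3.44e-14), followed by the natural killer receptor gene Klrd1 (-3.47 ± 0.23) and by Pxylp1 (-3.30 ± 0.14), Lypd6b (-3.29 ± 0.12), Igfbp4 (-3.22 ± 0.12) and Vipr1 (-3.15 ± 0.15). Cd24a did not pass (0.64 ± 0.24, adjusted p = 0.0507), but passed, at 0.68 to 0.74, without replicate 1 of any Foxp3+ group, replicate 3 of any Foxp3- group or replicate 2 of Foxp3- CD24lo. In all, 5555 genes changed (30.5%), 2637 up and 2918 down, and with a 2-fold minimum 440 up and 290 down.

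Treg signature genes, which mark Tregs in mouse tissues, were higher almost throughout: of 23 measured, 22 rose and 0 fell (22 and 0 over the list alone, camera adjusted p = 4.16e-36). Icos was the member that did not pass (-0.04 ± 0.19), and without both CD24lo groups, left out after the values were seen, it was higher (0.64, adjusted p = 0.0408). Among NF-kB and TNF receptor genes, 14 of 17 rose and 1 fell (15 and 1 over the list alone, camera adjusted p = 3.44e-17), with Tnfrsf4 (2.86 ± 0.10) and Tnfrsf18 (2.23 ± 0.08) after Cd83. IL-2 signals through STAT5, and 12 of 16 IL-2 and STAT5 targets rose and 2 fell (12 and 2 over the list alone, camera adjusted p = 1.1e-09), including Cish (2.88 ± 0.08). Of 16 apoptosis regulators, 11 rose and 2 fell (11 and 2 over the list alone, camera adjusted p = 0.000228), led by Bcl2l1 (0.98 ± 0.09), Birc2 (0.89 ± 0.08) and Pmaip1 (2.35 ± 0.22). Genes induced by T cell receptor signalling divided, 12 up and 6 down (12 and 6 over the list alone, camera adjusted p = 0.0426, adjusted p = 0.269 with an estimated correlation, adjusted p = 0.103 without dim genes and 0.0994 with the mean of all probe sets), with Nr4a3 higher (1.70 ± 0.07) and Tnfsf11 lower (-0.85 ± 0.11).

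Cell cycle genes were lower in Foxp3+ cells: 21 of 23 fell and 0 rose (0 and 22 over the list alone, camera adjusted p = 1.48e-08, adjusted p = 0.253 with an estimated correlation), Stmn1 by the smallest p (-1.56 ± 0.11). Natural killer (NK) and NKT cell markers fell in 6 of 6 cases and rose in 0 (0 and 6 over the list alone, camera adjusted p = 1.52e-06), with Zbtb16 (-2.74 ± 0.23) and Klrk1 (-1.53 ± 0.13). Antigen-presenting cell markers fell in 9 of 13 and rose in 0 (0 and 9 over the list alone, camera adjusted p = 0.000681, adjusted p = 0.236 with an estimated correlation). Naive T cell genes had 2 up and 8 down of 14 (3 and 8 over the list alone, camera adjusted p = 0.00546, adjusted p = 0.236 with an estimated correlation). Mature thymocyte and egress genes had 11 up and 4 down of 20 (12 and 4 over the list alone, camera adjusted p = 0.00546, adjusted p = 0.236 with an estimated correlation). For immature thymocyte genes it was 1 up and 8 down of 21 (2 and 8 over the list alone, camera adjusted p = 0.0426, adjusted p = 0.436 with an estimated correlation, adjusted p = 0.0575 with quantile normalization and 0.112 without dim genes). Foxo1 (0.81 ± 0.06) and Ccr9 (-1.10 ± 0.09) were examples from the last pair of lists.

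The following lists were not called in the averaged comparison. DNA methylation and demethylation genes held 8 higher and 7 lower of 23 (8 and 7 over the list alone, camera adjusted p = 0.985, median 0.04, mean -0.05 and test direction up), with Dnmt3b (-0.89 ± 0.07) and Tet1 (-1.17 ± 0.11) down and Mbd2 unchanged by the test (0.04 ± 0.06). Interferon response genes held 8 higher and 6 lower of 21 (9 and 7 over the list alone, camera adjusted p = 0.985, median -0.06, mean -0.04 and test direction up). Effector Treg and trafficking genes held 10 and 8 of 26 (11 and 8 over the list alone, camera adjusted p = 0.0645), and cytokine and helper lineage genes 5 and 11 of 19 (5 and 11 over the list alone, camera adjusted p = 0.0645, adjusted p = 0.0274 with the mean of all probe sets). Ccr6 was 4.43 ± 0.10 and Il21 -2.70 ± 0.13. For dissociation stress genes the numbers were 1 and 3 of 16 (1 and 3 over the list alone, camera adjusted p = 0.635), and for double-positive thymocyte markers 0 and 2 of 10 (0 and 2 over the list alone, camera adjusted p = 0.603). They were, for CD8 T cell markers 2 and 2 of 6 (2 and 2 over the list alone, camera adjusted p = 0.985, median -0.03, mean 0.05 and test direction down), and for B cell markers 2 and 2 of 9 (2 and 2 over the list alone, camera adjusted p = 0.985, median 0.02, mean -0.05 and test direction up). Thymic epithelium markers had 0 and 1 of 8 (0 and 1 over the list alone, camera adjusted p = 0.982), and erythroid markers 0 and 0 of 4 (0 and 0 over the list alone, camera adjusted p = 0.985, median 0.00, mean -0.01 and test direction up).

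At CD24hi, the least mature gate, Foxp3 was 6.27 ± 0.17 and Il2ra 5.76 ± 0.20 higher in Foxp3+ cells, while Cd24a did not pass (-0.59 ± 0.42, adjusted p = 0.419, and 0.0473 with the replicate number as a block). Plagl1 (6.23 ± 0.23), the neuropilin gene Nrp1 (5.03 ± 0.23) and Ctla4 (4.85 ± 0.32) were also among the largest rises. Chl1 (-4.60 ± 0.26), Chdh (-4.16 ± 0.32) and Adgrg3 (-3.39 ± 0.17) fell most, all with adjusted p of at most 4.25e-10. Lower too were Rag1 (-2.57 ± 0.25) and Ccr9 (-2.72 ± 0.16) (adjusted p of at most 2.99e-08). Of the 21 immature thymocyte genes, 0 rose and 9 fell (0 and 11 over the list alone, camera adjusted p = 7.65e-07, adjusted p = 0.0705 with an estimated correlation). Double-positive thymocyte markers fell in 4 of 10 and rose in 0 (0 and 4 over the list alone, camera adjusted p = 0.0139, adjusted p = 0.116 with an estimated correlation, adjusted p = 0.0626 without dim genes). Effector Treg and trafficking genes rose in 12 and fell in 2 of 26 (15 and 2 over the list alone, camera adjusted p = 1.53e-05, adjusted p = 0.106 with an estimated correlation), with Itgae, the CD103 gene, at 4.55 ± 0.42. Changed genes numbered 3280, 1524 up and 1756 down, or 1356 up and 1250 down without Foxp3+ CD24hi replicate 2.

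Cell cycle genes at CD24hi did not pass as a list, with 0 up and 3 down of 23 (0 and 3 over the list alone, camera adjusted p = 0.0588, adjusted p = 0.0121 with the replicate number as a block, adjusted p = 0.0294 with compared groups alone). Interferon response genes had 10 up and 1 down of 21 (10 and 1 over the list alone, camera adjusted p = 0.00403, adjusted p = 0.229 with an estimated correlation), with Mx1 up (1.63 ± 0.19) and Oas2 down (-1.22 ± 0.20). No NK and NKT cell marker passed, 0 up and 0 down of 6 (0 and 0 over the list alone, camera adjusted p = 0.62).

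At CD24int, Treg genes were again far higher, with Foxp3 at 6.25 ± 0.17, Socs2 at 5.83 ± 0.22, Nrp1 at 5.67 ± 0.23 and Cd83 at 5.27 ± 0.19 (adjusted p of at most 2.51e-15). The largest falls were in Igfbp4 (-3.96 ± 0.21), Lypd6b (-3.91 ± 0.21), Pxylp1 (-3.91 ± 0.24) and Pde3b (-3.90 ± 0.34) (adjusted p of at most 3.8e-09). Il2ra was 5.94 ± 0.20 and Cd24a did not pass (0.87 ± 0.42). All 23 Treg signature genes rose (23 and 0 over the list alone, camera adjusted p = 7.09e-51). Naive T cell genes fell in 8 of 14 and rose in 0 (0 and 8 over the list alone, camera adjusted p = 3.49e-07), including Lef1 (-0.98 ± 0.12). Cell cycle genes fell in 17 of 23 and rose in 0 (0 and 23 over the list alone, camera adjusted p = 1.11e-13, adjusted p = 0.0988 with an estimated correlation), with Stmn1 at -1.93 ± 0.19 and Mcm4 at -0.81 ± 0.13. Of 6 NK and NKT cell markers, 4 fell and 0 rose (0 and 5 over the list alone, camera adjusted p = 3.41e-05, adjusted p = 0.0553 with an estimated correlation). Antigen-presenting cell markers fell in 6 and rose in 0 of 13 (0 and 7 over the list alone, camera adjusted p = 0.00144, adjusted p = 0.218 with an estimated correlation). The count of changed genes was 2779, 1575 up and 1204 down.

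At CD24lo, the gate with the least CD24, the largest falls in Foxp3+ cells were in the receptor genes Klrd1 (-7.20 ± 0.39) and Klra5 (-7.07 ± 0.47), the gamma delta T cell receptor segments Trgv4 (-6.39 ± 0.41) and Trgv1 (-6.18 ± 0.46), and App (-6.27 ± 0.43) and Cxcr6 (-6.00 ± 0.50). Zbtb16, which encodes the NKT lineage factor PLZF (-5.99 ± 0.39), and Il4 (-5.83 ± 0.38) fell too, all with adjusted p of at most 9.31e-10. All 6 measured NK and NKT cell markers fell (0 and 6 over the list alone, camera adjusted p = 8.3e-11). Of 13 antigen-presenting cell markers, 9 fell and 0 rose (0 and 9 over the list alone, camera adjusted p = 1.74e-05, adjusted p = 0.0897 with an estimated correlation). Foxp3 (6.08 ± 0.17), Il2ra (5.85 ± 0.20), Plagl1 (6.14 ± 0.23), Penk (5.46 ± 0.24) and Dusp4 (5.07 ± 0.33) rose, and Cd24a rose too (1.62 ± 0.42, adjusted p = 0.00569). Without replicate 1 of Foxp3- CD24lo, Cd24a did not pass (1.16, adjusted p = 0.0642). The gates may be unmatched in CD24, and 3829 genes changed, 1792 up and 2037 down.

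Effector Treg and trafficking genes at CD24lo had 8 up and 15 down of 26 (8 and 16 over the list alone, camera adjusted p = 0.00872, adjusted p = 0.342 with an estimated correlation), with Ccr6 higher (4.90 ± 0.18) and Ccr10 (-4.60 ± 0.23) and Tbx21 (-3.72 ± 0.26) lower. Cytokine and helper lineage genes had 4 up and 10 down of 19 (4 and 11 over the list alone, camera adjusted p = 0.00602, adjusted p = 0.0897 with an estimated correlation, adjusted p = 0.0676 without dim genes). Of DNA methylation and demethylation genes, 6 rose and 5 fell of 23 (6 and 5 over the list alone, camera adjusted p = 0.805, median 0.11, mean -0.02 and test direction up), among them Dnmt3b (-1.75 ± 0.13) and Dnmt3a (0.52 ± 0.10). Dnmt3a did not pass with the mean of all its probe sets (0.38, adjusted p = 0.17). Across all 18194 genes, the Foxp3 difference at CD24hi correlated with that at CD24int at r = 0.75 and with that at CD24lo at r = 0.55. The arrays behind each pair were separate, and genes are not independent replicates.

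Lymph node Tregs were compared with lymph node naive T cells to describe mature peripheral cells. The integrin gene Itgae was 85.7-fold higher in Tregs (6.42 ± 0.42, adjusted p = 2.58e-11), Foxp3 5.72 ± 0.17, Il2ra 5.45 ± 0.20, Ctla4 5.42 ± 0.32 and Klrg1 5.13 ± 0.20 (adjusted p of at most 2.56e-12). Pdlim4 (-5.24 ± 0.23), Pde3b (-4.82 ± 0.34), Lypd6b (-4.69 ± 0.21) and Vipr1 (-4.55 ± 0.26) fell most. Klrd1 (-4.36 ± 0.39), App (-4.19 ± 0.43), Cxcr6 (-4.04 ± 0.50) and Zbtb16 (-2.19 ± 0.39), named above for CD24lo, were lower in Tregs here too. Of 6 NK and NKT cell markers, 3 fell and 0 rose (0 and 5 over the list alone, camera adjusted p = 0.00154, adjusted p = 0.151 with an estimated correlation). Cd24a did not pass (1.11 ± 0.42, adjusted p = 0.0998), though it did with the block (adjusted p = 0.00048) and without naive replicate 3 (1.46, adjusted p = 0.0412). All 23 Treg signature genes rose (23 and 0 over the list alone, camera adjusted p = 8.65e-70). Of 26 effector Treg and trafficking genes, 23 rose against 1 that fell (24 and 2 over the list alone, camera adjusted p = 2.64e-32). Naive T cell genes fell in 9 and rose in 2 of 14 (2 and 10 over the list alone, camera adjusted p = 2.09e-10), led by Tdrp (-2.64 ± 0.14) and with Actn1 at -1.72 ± 0.14. Cell cycle genes were higher here, 8 up and 0 down of 23 (11 and 0 over the list alone, camera adjusted p = 1.48e-07, adjusted p = 0.313 with an estimated correlation), with Tk1 at 1.95 ± 0.30. The count was 2250 genes, 1458 up and 792 down.

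The lymph node comparison gave 570 genes at least 2-fold higher in Tregs and 162 at least 2-fold lower, which were then followed in thymus arrays that had no part in choosing them. In precursors against Foxp3- CD24hi cells, 251 of the 570 rose (44%) and 30 fell, with a median of 0.51 (camera p = 3.72e-44, and 2.3e-05 with an estimated correlation). In Foxp3+ against Foxp3- cells, 341 rose at CD24hi (59.8%), 418 at CD24int (73.3%) and 338 at CD24lo (59.3%), with 28, 30 and 91 that fell. Of the 162 genes lower in lymph node Tregs, 63 fell in precursors (38.9%), 104 at CD24hi (64.2%), 139 at CD24int (85.8%) and 120 at CD24lo (74.1%), while 16, 7, 1 and 7 rose. The list comes from the same series, so it is not independent evidence. Across genes, the lymph node difference correlated at r = 0.51 with the Foxp3 difference at CD24hi, at 0.45 with that at CD24lo and at 0.41 with the precursor difference.

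**Figure D3:**
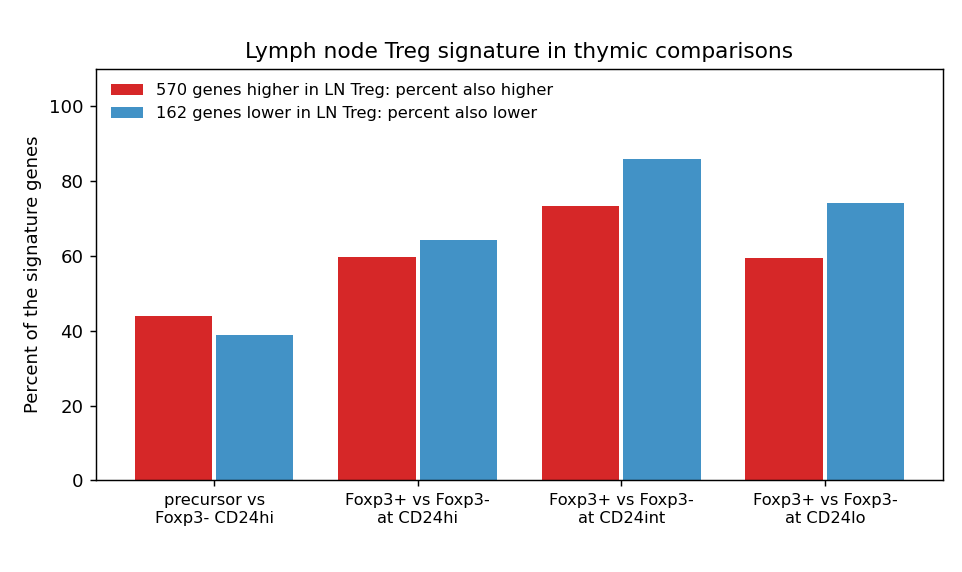
Percent of the genes at least 2-fold higher (570) or lower (162) in lymph node Tregs than in naive cells that passed in the same direction in each thymus comparison. The share of higher genes ran from 44% in precursors to 73.3% at CD24int.

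Maturation of Foxp3+ thymocytes was followed by CD24lo against CD24hi. Cd24a was lower (-2.72 ± 0.42, adjusted p = 0.000281), while Foxp3 (-0.17 ± 0.17) and Il2ra (-0.11 ± 0.20) did not pass. The secreted proteoglycan gene Prg4 rose most (3.00 ± 0.22, adjusted p = 1.22e-08), with Axl (2.64 ± 0.21), S100a4 (2.57 ± 0.49), Il1r2 (2.56 ± 0.22), Cxcr5 (2.41 ± 0.26) and Maf (2.41 ± 0.43) also up and Trpm1 (-2.26 ± 0.32), Mcf2l (-2.03 ± 0.23) and Lox (-2.02 ± 0.41) down. Of 26 effector Treg and trafficking genes, 10 rose and 0 fell (14 and 0 over the list alone, camera adjusted p = 3.44e-12), among them Klrg1 (1.60 ± 0.20), Ccr6 (1.32 ± 0.18) and Fgl2 (2.20 ± 0.35). Of Treg signature genes, 9 rose and 0 fell of 23 (11 and 0 over the list alone, camera adjusted p = 1.51e-10), including Capg (1.03 ± 0.11) and Ebi3 (1.84 ± 0.23). In total 564 genes changed, 417 up and 147 down, and 1300 with the replicate number as a block. Without Foxp3+ CD24lo replicate 2 or 3 the count was 346 (264 up, 82 down) or 364 (263 up, 101 down). It was 385 (310 up, 75 down) without CD24hi replicate 1 and 410 (331 up, 79 down) without CD24lo replicate 1.

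Immature thymocyte genes had 1 up and 2 down of 21 in mature Foxp3+ cells (1 and 3 over the list alone, camera adjusted p = 0.00337, adjusted p = 0.27 with an estimated correlation), with Sox4 down (-1.20 ± 0.23) and Tdgf1 up (1.69 ± 0.31). Mature thymocyte and egress genes were called higher as a list although 1 of 20 rose and 0 fell (3 and 0 over the list alone, camera adjusted p = 0.00243, adjusted p = 0.199 with an estimated correlation), that gene being Il6ra (2.02 ± 0.20). Cell cycle genes had 0 up and 2 down of 23 (0 and 4 over the list alone, camera adjusted p = 5.4e-05, adjusted p = 0.419 with an estimated correlation), Stmn1 at -1.02 ± 0.19 and Mcm5 at -0.56 ± 0.13. Mcm5 did not pass without Foxp3+ CD24hi replicate 1 (-0.52) or 3 (-0.50) or CD24lo replicate 2 (-0.51), with the mean of all its probe sets (-0.38, adjusted p = 0.165) or in a fit of the 6 arrays alone (adjusted p = 0.0616). NK and NKT cell markers were called lower as a list with 0 up and 0 down of 6 (0 and 0 over the list alone, camera adjusted p = 0.0415, adjusted p = 0.417 with an estimated correlation, adjusted p = 0.0646 with the replicate number as a block, adjusted p = 0.0518 with quantile normalization and 0.128 without dim genes).

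Steps between adjacent gates changed few genes in Foxp3+ cells. From CD24hi to CD24int, S100a4 (2.51 ± 0.49), Fgl2 (1.94 ± 0.35), Cxcr3 (1.82 ± 0.38), Il1r2 (1.72 ± 0.22), Axl (1.54 ± 0.21) and Prg4 (1.47 ± 0.22) rose, with adjusted p of at most 0.0298, and Prr5l (-1.28 ± 0.27) and Mcf2l (-1.12 ± 0.23) fell. Cd24a (-1.26 ± 0.42), Foxp3 (0.00 ± 0.17) and Il2ra (0.08 ± 0.20) did not pass, although Cd24a did with the replicate number as a block (adjusted p = 0.00308). Treg signature genes had 3 up and 0 down of 23 (8 and 0 over the list alone, camera adjusted p = 1.19e-09). Effector Treg and trafficking genes had 6 up and 0 down of 26 (12 and 0 over the list alone, camera adjusted p = 1.75e-14). CD8 T cell markers were called higher as a list, 1 up and 0 down of 6 (1 and 0 over the list alone, camera adjusted p = 0.0324, adjusted p = 0.1 with an estimated correlation, adjusted p = 0.0652 without dim genes). Immature thymocyte genes did not pass as a list, 0 up and 0 down of 21 (1 and 2 over the list alone, camera adjusted p = 0.0526, adjusted p = 0.0275 with the replicate number as a block, adjusted p = 0.0327 without dim genes, 0.0492 with the intensity trend and 0.0211 with compared groups alone). The count was 52 (44 up, 8 down), 210 with the block and 0 in a fit of the 6 arrays alone (1068 at an unadjusted p under 0.05). It was 20 without Foxp3+ CD24int replicate 1, where Cxcr3 (1.61), S100a4 (2.48), Prr5l (-1.34) and Mcf2l (-1.04) did not pass. Without replicate 2 of that group it was 14, and Cxcr3 (1.71), S100a4 (2.26), Fgl2 (1.72), Prr5l (-1.17) and Mcf2l (-1.06) did not pass. Without Foxp3+ CD24hi replicate 3 it was 25, and Cxcr3 (1.30), S100a4 (1.91), Fgl2 (1.5), Prr5l (-0.93) and Mcf2l (-0.86) did not pass. Prr5l (-1.35) and Mcf2l (-1.10) did not pass without Foxp3+ CD24hi replicate 1.

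From CD24int to CD24lo, Foxp3+ cells gained Prg4 (1.53 ± 0.22, adjusted p = 0.00418) and Arrdc4 (0.90 ± 0.12, adjusted p = 0.00139) and lost Fibcd1 (-1.05 ± 0.18, adjusted p = 0.0386). These were the 3 genes called by limma, against 819 at an unadjusted p under 0.05 and 23 with the block. A fit of the 6 arrays alone called 0 (722 at an unadjusted p under 0.05). Leaving out Foxp3+ CD24int replicate 1, 2 or 3 gave 1, 7 or 1. Prg4 did not pass without CD24int replicate 1 (1.39) or 3 (1.41) or CD24lo replicate 2 (1.36), and Fibcd1 without any of these (-0.98, -0.92 and -0.92) or without CD24lo replicate 1 (-1.13) or 3 (-1.10). Cd24a (-1.45 ± 0.42), Foxp3 (-0.17 ± 0.17) and Il2ra (-0.18 ± 0.20) did not pass, although Cd24a did with the block (adjusted p = 0.004). Treg signature genes were called higher as a list with 0 up and 0 down (0 and 0 over the list alone, camera adjusted p = 0.0126, adjusted p = 0.505 with an estimated correlation), and interferon response genes lower with 0 up and 0 down (0 and 0 over the list alone, camera adjusted p = 0.0126, adjusted p = 0.669 with an estimated correlation). With the block, adjusted p passed as well for immature thymocyte genes (0.0219), cell cycle genes (0.0219), naive T cell genes (0.0219), mature thymocyte and egress genes (0.043) and DNA methylation and demethylation genes (0.043).

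Maturation of Foxp3- thymocytes was followed from CD24hi to CD24lo. Klra5 rose by 6.61 ± 0.47, S100a6 by 6.34 ± 0.50, Klrd1 by 6.29 ± 0.39, Zbtb16 by 5.72 ± 0.39, Ifng by 5.71 ± 0.44 and Il4 by 5.71 ± 0.38 (adjusted p of at most 4.96e-10). The falls included Cd24a (-4.93 ± 0.42), Rag1 (-3.28 ± 0.25) and Ccr9 (-2.96 ± 0.16) (adjusted p of at most 2.21e-09), beside Chl1 (-3.61 ± 0.26), Tmcc3 (-3.59 ± 0.17) and F13a1 (-3.43 ± 0.22). Foxp3 (0.02 ± 0.17) and Il2ra (-0.20 ± 0.20) did not pass. All 6 NK and NKT cell markers rose (6 and 0 over the list alone, camera adjusted p = 8.49e-10). Of 26 effector Treg and trafficking genes, 19 rose and 1 fell (20 and 1 over the list alone, camera adjusted p = 1.81e-20), with Ccr10 at 4.35 ± 0.23 and Tbx21 at 4.75 ± 0.26. Counts were 3042 genes, 1666 up and 1376 down.

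**Figure D4:**
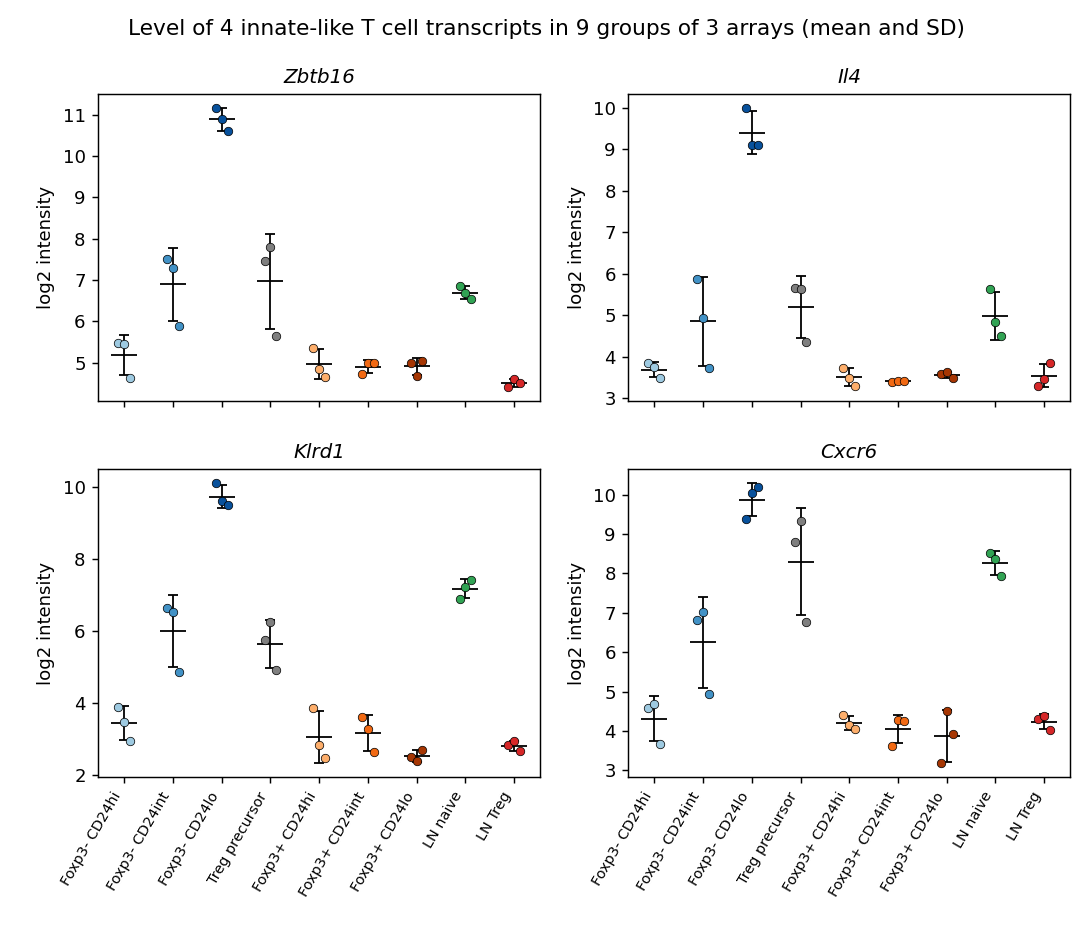
Log2 intensity of Zbtb16, Il4, Klrd1 and Cxcr6 in each array, with the mean and SD of each group (n = 3). Zbtb16 was 5.72 and Il4 5.71 higher in Foxp3- CD24lo than in Foxp3- CD24hi cells.

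Immature thymocyte genes fell in 15 and rose in 3 of 21 on the way from CD24hi to CD24lo in Foxp3- cells (4 and 15 over the list alone, camera adjusted p = 9.45e-11). Naive T cell genes fell in 8 and rose in 2 of 14 (3 and 8 over the list alone, camera adjusted p = 3.91e-05, adjusted p = 0.05 with an estimated correlation), with Bach2 at -1.75 ± 0.12 and Lef1 at -1.12 ± 0.12. Cytokine and helper lineage genes rose in 10 and fell in 4 of 19 (10 and 4 over the list alone, camera adjusted p = 0.000683). Antigen-presenting cell markers rose in 6 and fell in 0 of 13 (7 and 0 over the list alone, camera adjusted p = 0.000293, adjusted p = 0.174 with an estimated correlation). Dissociation stress genes, a list for handling, rose in 5 and fell in 0 of 16 (5 and 0 over the list alone, camera adjusted p = 0.0166, adjusted p = 0.372 with an estimated correlation, adjusted p = 0.0904 without dim genes). Double-positive thymocyte markers fell in 6 and rose in 1 of 10 (1 and 6 over the list alone, camera adjusted p = 8.93e-05). Lists for natural killer cells and innate-like T cells, written after the values were seen, had 3 of 6 and 11 of 11 measured genes higher and 0 lower, with medians of 0.39 and 2.26.

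Between CD24hi and CD24int, Foxp3- cells lost Rag1 (-3.11 ± 0.25), Cd24a (-2.73 ± 0.42), Asb2 (-2.39 ± 0.14) and Ccr9 (-2.16 ± 0.16), with adjusted p of at most 0.000142. They gained Klrd1 (2.56 ± 0.39), S100a6 (2.36 ± 0.50), Ifng (2.33 ± 0.44) and Ahnak (2.11 ± 0.27) (adjusted p of at most 0.00398) and the egress receptor gene S1pr1 (1.75 ± 0.23). Foxp3 (0.02 ± 0.17) and Il2ra (-0.10 ± 0.20) did not pass. Interferon response genes rose in 15 and fell in 0 of 21 (18 and 1 over the list alone, camera adjusted p = 2.98e-18), among them Ifit3 (1.17 ± 0.17). Mature thymocyte and egress genes rose in 9 and fell in 0 of 20 (15 and 0 over the list alone, camera adjusted p = 8.12e-15). Genes induced by T cell receptor signalling had 1 up and 8 down of 20 (1 and 11 over the list alone, camera adjusted p = 0.000134). Changed genes came to 911, 411 up and 500 down, and to 1822 with the block. With quantile normalization 457 were up and 434 down. They were 421 and 375, 263 and 363, or 338 and 296 without CD24hi replicate 1, CD24hi replicate 3 or CD24int replicate 2. Of 6 NK and NKT cell markers, 3 rose and 0 fell (4 and 0 over the list alone, camera adjusted p = 2.57e-05). Double-positive thymocyte markers had 1 up and 3 down of 10 (1 and 4 over the list alone, camera adjusted p = 0.000763). Antigen-presenting cell markers rose in 3 and fell in 0 of 13 (5 and 0 over the list alone, camera adjusted p = 0.000326, adjusted p = 0.151 with an estimated correlation).

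Between CD24int and CD24lo, Foxp3- cells gained Prg4 (4.85 ± 0.22), Klrb1a (4.85 ± 0.17), Klra5 (4.73 ± 0.47), Trgv4 (4.65 ± 0.41) and Il4 (4.55 ± 0.38) (adjusted p of at most 4.92e-08). Cd24a (-2.20 ± 0.42), Tubb2b (-2.17 ± 0.35) and Tmcc3 (-2.01 ± 0.17) fell, and Foxp3 (0.00 ± 0.17) and Il2ra (-0.10 ± 0.20) did not pass. Mature thymocyte and egress genes went down in this step, 10 of 20 against 1 up (2 and 12 over the list alone, camera adjusted p = 5.27e-06), with Ccr7 at -1.24 ± 0.15 and Foxo1 at -0.78 ± 0.11. Of 14 naive T cell genes, 11 fell and 0 rose (2 and 11 over the list alone, camera adjusted p = 1.12e-10). Interferon response genes had 1 up and 7 down of 21 (2 and 10 over the list alone, camera adjusted p = 0.00129, adjusted p = 0.193 with an estimated correlation). Effector Treg and trafficking genes had 20 up and 0 down of 26 (21 and 0 over the list alone, camera adjusted p = 7.79e-24). Of 10 double-positive thymocyte markers, 0 rose and 2 fell (0 and 2 over the list alone, camera adjusted p = 0.0341, adjusted p = 0.193 with an estimated correlation). Among 6 NK and NKT cell markers, 5 rose and 0 fell (5 and 0 over the list alone, camera adjusted p = 7.04e-08). The step changed 2182 genes, 1430 up and 752 down, and 3407 with the block.

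Maturation was compared as an interaction, the CD24lo minus CD24hi change in Foxp3+ cells minus that in Foxp3- cells. The most negative differences were in Klra5 (-6.83 ± 0.66), Klrd1 (-6.82 ± 0.55), Trgv4 (-5.93 ± 0.58), Cxcr6 (-5.88 ± 0.70), Trgv1 (-5.86 ± 0.65), Zbtb16 (-5.77 ± 0.55), Spry2 (-5.67 ± 0.48) and Il4 (-5.65 ± 0.53), with adjusted p of at most 1.81e-06. F13a1 (4.05 ± 0.31), Tmcc3 (3.35 ± 0.24), Chl1 (3.11 ± 0.36), Il1r2 (2.82 ± 0.31), Axl (2.72 ± 0.30) and Rag1 (2.71 ± 0.36) had positive differences (adjusted p of at most 8.13e-06). So did Cd24a (2.21 ± 0.60, adjusted p = 0.0179), which declined less in Foxp3+ cells. Cd24a did not pass without Foxp3+ CD24hi replicate 1 (1.99), Foxp3- CD24lo replicate 1 (1.75) or Foxp3+ CD24lo replicate 2 (2.08), or with the mean of all its probe sets (2.10, adjusted p = 0.0644). Foxp3 (-0.19 ± 0.24) and Il2ra (0.09 ± 0.29) did not pass. The test called 1554 genes, 744 with a positive and 810 with a negative difference, and 2490 with the block. Without replicate 3 of Foxp3+ CD24hi, Foxp3- CD24hi or Foxp3- CD24lo, 739, 707 or 721 were positive and 732, 698 or 699 negative. Of the 1554, 1251 had changed from CD24hi to CD24lo in Foxp3- cells without passing in Foxp3+ cells, 106 the other way round, and 31 in opposite directions in both. Maturation cannot be told apart here from other kinds of cell, or the wider Cd24a span, in the Foxp3- gates.

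Immature thymocyte genes had 9 positive and 0 negative differences of 21 (10 and 0 over the list alone, camera adjusted p = 2.38e-08), with Ccr9 at 2.65 ± 0.23. All 6 NK and NKT cell markers had negative differences (0 and 6 over the list alone, camera adjusted p = 5.85e-13). Of 26 effector Treg and trafficking genes, 17 had negative differences against 4 positive (5 and 19 over the list alone, camera adjusted p = 2.03e-10). Naive T cell genes had 7 positive and 1 negative of 14 (7 and 1 over the list alone, camera adjusted p = 0.000177, adjusted p = 0.112 with an estimated correlation). For double-positive thymocyte markers it was 3 and 0 of 10 (4 and 0 over the list alone, camera adjusted p = 0.00034). Antigen-presenting cell markers had 0 positive and 3 negative of 13 (0 and 6 over the list alone, camera adjusted p = 0.000121, adjusted p = 0.142 with an estimated correlation). Treg signature genes divided, 6 positive and 10 negative of 23 (7 and 10 over the list alone, camera adjusted p = 0.198), with Gpr83 positive (2.30 ± 0.29) and Capg negative (-2.13 ± 0.16). Across genes, the maturation changes of Foxp3+ and Foxp3- cells correlated at r = 0.31 for CD24lo against CD24hi and at r = 0.08 for CD24int against CD24hi. With CD24int in place of CD24lo, an alternative chosen after the values were seen, the interaction called 281 genes, 184 positive and 97 negative. In it Klra5 (-1.84), Trgv4 (-1.32), Cxcr6 (-2.09), Trgv1 (-1.20), Zbtb16 (-1.77), Spry2 (-1.49), Il4 (-1.25), Chl1 (1.35), Cd24a (1.46), Gpr83 (0.69) and Capg (-0.23) did not pass.

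Precursors were set against Foxp3- CD24hi thymocytes, the conventional thymic gate with the most CD24. Il2ra was 13.3-fold higher in precursors (3.74 ± 0.20, adjusted p = 6.21e-12), while Foxp3 (0.17 ± 0.17, adjusted p = 0.71) and Cd24a (0.81 ± 0.42, adjusted p = 0.317, or 0.011 with the block) did not pass. Penk (4.29 ± 0.24), Car8 (4.27 ± 0.20), Xcl1 (4.20 ± 0.46), Cxcr6 (3.99 ± 0.50), Plagl1 (3.97 ± 0.23) and Dusp4 (3.75 ± 0.33) were among the largest rises, with adjusted p of at most 3.55e-06. Kif23 (-1.99 ± 0.41), Acvrl1 (-1.96 ± 0.29), Ampd1 (-1.87 ± 0.25) and Itgb3 (-1.80 ± 0.20) fell most (adjusted p of at most 0.00181). Treg signature genes rose in 17 and fell in 2 of 23 (17 and 2 over the list alone, camera adjusted p = 1.27e-28), including Il2rb (3.22 ± 0.18) and Ikzf2 (2.91 ± 0.17). Genes induced by T cell receptor signalling rose in 10 and fell in 2 of 20 (10 and 2 over the list alone, camera adjusted p = 5.96e-05), with Nr4a3 (1.41 ± 0.13) and Pdcd1 (1.72 ± 0.21). Precursors differed in 1658 genes, 925 up and 733 down, and in 2671 with the block. Against Foxp3- CD24int cells the count was 2490 (1558 up, 932 down). There Kif23 did not pass (-1.18, adjusted p = 0.0607) and Cd24a was higher (3.53, adjusted p = 1.11e-06).

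NF-kB and TNF receptor genes were higher in precursors, 10 up and 1 down of 17 (12 and 2 over the list alone, camera adjusted p = 4.24e-15), with Cd83 (3.28 ± 0.19) and Tnfrsf1b (2.13 ± 0.16). IL-2 and STAT5 targets had 7 up and 2 down of 16 (8 and 2 over the list alone, camera adjusted p = 6.28e-08), Lta at 1.90 ± 0.12. Double-positive thymocyte markers rose in 5 and fell in 0 of 10 (5 and 1 over the list alone, camera adjusted p = 0.000667), with Rag1 (2.21 ± 0.25), Ptcra (1.75 ± 0.32) and Arpp21 (1.71 ± 0.30). Among 14 naive T cell genes, 7 fell and 0 rose (0 and 8 over the list alone, camera adjusted p = 1.37e-08). Interferon response genes had 0 up and 8 down of 21 (1 and 8 over the list alone, camera adjusted p = 0.00011, adjusted p = 0.0871 with an estimated correlation). NK and NKT cell markers had 3 up and 0 down of 6 (3 and 0 over the list alone, camera adjusted p = 0.000456, adjusted p = 0.0871 with an estimated correlation), with Zbtb16 at 1.79 ± 0.39, which was 0.07 (adjusted p = 0.947) against Foxp3- CD24int cells. In a fit of the 6 arrays alone neither Arpp21 (adjusted p = 0.0807) nor Zbtb16 (adjusted p = 0.0917) passed. Cell cycle genes did not pass as a list, 1 up and 0 down of 23 (1 and 0 over the list alone, camera adjusted p = 0.0605, adjusted p = 0.00659 with the replicate number as a block, adjusted p = 0.0388 with the mean of all probe sets and 0.0416 with compared groups alone). Antigen-presenting cell markers did pass, 0 up and 0 down of 13 (0 and 0 over the list alone, camera adjusted p = 0.0383, adjusted p = 0.428 with an estimated correlation, adjusted p = 0.0507 with the replicate number as a block, adjusted p = 0.0515 with quantile normalization and 0.14 without dim genes). The precursor difference correlated with the Foxp3 difference at CD24lo at r = 0.11 across genes.

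Foxp3+ CD24hi cells were compared with precursors to describe the step at which Foxp3 appears. Foxp3 was 68.6-fold higher (6.10 ± 0.17, adjusted p = 2.62e-18) and Il2ra 4.07-fold higher (2.02 ± 0.20, adjusted p = 1.03e-07), and Cd24a was lower (-1.40 ± 0.42, adjusted p = 0.0236). Cd24a did not pass without Foxp3+ CD24hi replicate 1 (-1.17) or 2 (-1.35) or precursor replicate 3 (-1.15), or with the mean of all its probe sets (-1.42, adjusted p = 0.0525). Cyp4f18 (3.84 ± 0.25), Cavin1 (3.08 ± 0.26), Socs2 (2.95 ± 0.22), Gpr83 (2.72 ± 0.20) and Itgb8 (2.71 ± 0.18) rose (adjusted p of at most 7.12e-09). Rag1 fell most (-4.78 ± 0.25, adjusted p = 4.15e-12), followed by Cxcr6 (-4.10 ± 0.50), Chl1 (-2.86 ± 0.26), Pou2af1 (-2.81 ± 0.22) and Pde3b (-2.77 ± 0.34). Treg signature genes rose in 17 and fell in 0 of 23 (17 and 1 over the list alone, camera adjusted p = 7.95e-18), while Ikzf2 did not pass (0.30 ± 0.17). Double-positive thymocyte markers fell in 6 and rose in 0 of 10 (0 and 7 over the list alone, camera adjusted p = 5.42e-07), with Dntt (-2.37 ± 0.31) and Ptcra (-2.03 ± 0.32). The comparison called 2917 genes, 1231 up and 1686 down, and 4443 with the block. Without Foxp3+ CD24hi replicate 2, 979 were up and 1075 down.

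Mature thymocyte and egress genes rose in 12 and fell in 0 of 20 from precursor to Foxp3+ CD24hi (14 and 1 over the list alone, camera adjusted p = 2.03e-09), including Itgb7 (1.27 ± 0.11) and Ms4a4b (1.05 ± 0.11). Interferon response genes rose in 13 and fell in 0 of 21 (18 and 0 over the list alone, camera adjusted p = 3.04e-11), including Usp18 (1.08 ± 0.15) and Irf9 (0.57 ± 0.09). IL-2 and STAT5 targets had 8 up and 3 down of 16 (11 and 3 over the list alone, camera adjusted p = 3.69e-06), with Pim1 at 2.50 ± 0.13. Cytokine and helper lineage genes had 3 up and 9 down of 19 (3 and 11 over the list alone, camera adjusted p = 0.00181, adjusted p = 0.054 with an estimated correlation, adjusted p = 0.0729 without dim genes), with Eomes up (1.42 ± 0.18) and Il2 down (-1.64 ± 0.22). NK and NKT cell markers had 0 up and 4 down of 6 (0 and 5 over the list alone, camera adjusted p = 0.000339, adjusted p = 0.088 with an estimated correlation). Of 13 antigen-presenting cell markers, 0 rose and 3 fell (0 and 5 over the list alone, camera adjusted p = 0.00988, adjusted p = 0.319 with an estimated correlation, adjusted p = 0.102 without dim genes). Cell cycle genes had 0 up and 5 down of 23 (0 and 5 over the list alone, camera adjusted p = 9.43e-05, adjusted p = 0.344 with an estimated correlation).

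Lymph node Tregs were set against Foxp3+ CD24lo thymocytes. Foxp3 (-0.01 ± 0.17), Il2ra (-0.17 ± 0.20) and Cd24a (0.37 ± 0.42) did not pass. Klrg1 rose most (3.22 ± 0.20, adjusted p = 1.69e-10), with S100a6 (3.18 ± 0.50), Ms4a1 (2.93 ± 0.29), Pou2af1 (2.83 ± 0.22) and S100a4 (2.81 ± 0.49) next (adjusted p of at most 0.000448). Scin (-3.31 ± 0.27), Cavin1 (-2.74 ± 0.26), Pla2g4f (-2.72 ± 0.23) and Kit (-2.52 ± 0.26) fell most (adjusted p of at most 4.45e-07). Among 26 effector Treg and trafficking genes, 17 rose and 2 fell (19 and 2 over the list alone, camera adjusted p = 3.32e-20), including Il10 (2.66 ± 0.23) and Anxa1 (2.33 ± 0.20). Interferon response genes fell in 11 and rose in 0 of 21 (0 and 15 over the list alone, camera adjusted p = 2.58e-17), with Usp18 (-1.30 ± 0.15) and Irf7 (-0.97 ± 0.13). NF-kB and TNF receptor genes fell in 5 and rose in 1 of 17 (2 and 6 over the list alone, camera adjusted p = 0.000628). B cell markers rose in 5 and fell in 0 of 9 (5 and 0 over the list alone, camera adjusted p = 2.49e-07), with Cd22 (1.21 ± 0.15) beside Ms4a1. Antigen-presenting cell markers rose in 4 and fell in 0 of 13 (4 and 0 over the list alone, camera adjusted p = 0.000313, adjusted p = 0.177 with an estimated correlation), with H2-Aa (2.26 ± 0.32) and H2-Ab1 (1.75 ± 0.24). B cells in lymph node sorts as a source of both lists were not tested. Of 10 double-positive thymocyte markers, 1 fell and 0 rose (0 and 2 over the list alone, camera adjusted p = 0.0197, adjusted p = 0.164 with an estimated correlation). Changes were called in 1078 genes, 573 up and 505 down, and in 1922 with the block. Without lymph node Treg replicate 2 or 3 or thymic replicate 3 they were 489, 397 or 420 up and 336, 426 or 328 down.

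Naive cells of the lymph node were compared with Foxp3- CD24lo thymocytes, which held innate-like transcripts, so organ and kind of cell cannot be told apart. Itgae fell most (-6.81 ± 0.42, adjusted p = 1.53e-11), and among the next were Klra5 (-6.37 ± 0.47), Jag1 (-5.21 ± 0.59), Cdh1 (-5.12 ± 0.37), Klrb1a (-5.06 ± 0.17) and Spry2 (-5.00 ± 0.34) (adjusted p of at most 3.87e-07). Dapl1 (3.00 ± 0.31), Ms4a1 (2.88 ± 0.29), Pde5a (2.73 ± 0.32), Pdlim4 (2.56 ± 0.23) and Cd55 (2.46 ± 0.23) rose (adjusted p of at most 6.99e-07). Foxp3 (0.35 ± 0.17), Il2ra (0.23 ± 0.20) and Cd24a (0.89 ± 0.42) did not pass, although Cd24a did with the block (adjusted p = 0.00365) and without naive replicate 1 (1.37, adjusted p = 0.0351). Among 20 mature thymocyte and egress genes, 13 rose and 1 fell (14 and 1 over the list alone, camera adjusted p = 2.13e-10). Naive T cell genes rose in 9 and fell in 2 of 14 (9 and 2 over the list alone, camera adjusted p = 6.74e-05, adjusted p = 0.0612 with an estimated correlation), with Tdrp at 1.73 ± 0.14. Cell cycle genes fell in 18 and rose in 0 of 23 (0 and 22 over the list alone, camera adjusted p = 1.86e-13, adjusted p = 0.0897 with an estimated correlation), including Mcm5 (-1.22 ± 0.13) and Tk1 (-1.95 ± 0.30). NK and NKT cell markers fell in 5 and rose in 0 of 6 (0 and 5 over the list alone, camera adjusted p = 1.45e-08). B cell markers, among them Ms4a1, rose in 4 and fell in 1 of 9 (5 and 1 over the list alone, camera adjusted p = 0.0253, adjusted p = 0.188 with an estimated correlation, adjusted p = 0.115 with compared groups alone). Dissociation stress genes fell in 4 and rose in 0 of 16 (0 and 5 over the list alone, camera adjusted p = 0.0138, adjusted p = 0.311 with an estimated correlation, adjusted p = 0.137 without dim genes). Apoptosis regulators had 7 up and 3 down of 16 (8 and 3 over the list alone, camera adjusted p = 0.0647, adjusted p = 0.04 with the replicate number as a block, adjusted p = 0.0397 with quantile normalization). The count was 2658 genes, 1097 up and 1561 down. Against Foxp3- CD24int cells, a reference chosen after the values were seen, it was 1558 (797 up, 761 down). There Jag1 (-0.67), Klrb1a (-0.21), Spry2 (-0.84) and Tdrp (0.31) did not pass.

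The difference between the last pair of comparisons set Tregs against conventional cells, with that limit on kind of cell. Itgae (6.55 ± 0.60), Ccr10 (6.49 ± 0.32), Klra5 (6.33 ± 0.66), Gzmb (6.26 ± 0.46) and S100a6 (6.21 ± 0.71) had the largest positive differences (adjusted p of at most 6.71e-07). Scin (-3.05 ± 0.37), Tnfsf8 (-2.73 ± 0.38), Cavin1 (-2.68 ± 0.36) and Ccr7 (-2.64 ± 0.22) had the largest negative differences (adjusted p of at most 1.3e-05). Foxp3 (-0.36 ± 0.24), Il2ra (-0.41 ± 0.29) and Cd24a (-0.52 ± 0.60) did not pass. Effector Treg and trafficking genes had 21 positive and 1 negative differences of 26 (23 and 1 over the list alone, camera adjusted p = 2.72e-33). Treg signature genes had 12 and 3 of 23 (12 and 3 over the list alone, camera adjusted p = 5e-07), and cell cycle genes 19 and 0 of 23 (23 and 0 over the list alone, camera adjusted p = 8.02e-17, adjusted p = 0.0651 with an estimated correlation). Mature thymocyte and egress genes had 0 positive and 10 negative of 20 (2 and 12 over the list alone, camera adjusted p = 3.65e-07). The NK and NKT cell markers had 5 positive and 0 negative of 6 (6 and 0 over the list alone, camera adjusted p = 3.67e-08). For antigen-presenting cell markers it was 4 and 0 of 13 (6 and 0 over the list alone, camera adjusted p = 0.000134, adjusted p = 0.129 with an estimated correlation). The test called 1996 genes, 1282 positive and 714 negative. Of these, 1189 had changed in conventional cells without passing in Tregs, 348 the other way round, and 223 in opposite directions in both. With CD24int in place of CD24lo, chosen after the values were seen, it called 661 (424 positive, 237 negative). In that test Klra5 (1.34, adjusted p = 0.425) and S100a6 (2.15, adjusted p = 0.11) did not pass.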

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

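The tests of cell sources, single arrays and shares were chosen only after the result was seen, with bounds and gene sets of the natural killer, single array and share tests revised later still, as were the genes singled out by the smallest p-values, while the interactions and the counts over other splits were planned.

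Tests of the interaction between Foxp3 class and maturation called 1554 genes whose CD24lo minus CD24hi change differed between Foxp3+ and Foxp3- cells. The smallest p-values belonged to Klrb1a (-5.36 ± 0.24, adjusted p = 2.04e-13), Niban1 (-4.73 ± 0.27, adjusted p = 2.51e-11) and Kctd15 (-3.09 ± 0.19, adjusted p = 1.01e-10). Klrb1a changed by -0.10 in Foxp3+ and 5.26 in Foxp3- cells, Niban1 by 0.75 and 5.48, and Kctd15 by -0.29 and 2.80. With CD24int in place of CD24lo, differences were -0.32 for Klrb1a and -0.19 for Kctd15, and neither passed. Of 100 regroupings within each class, 6 gave at least as many genes, the real one at 1554 and the highest other at 2730, so that chance could not be excluded by this count. Among 21 others that parted as many same-numbered pairs the highest was also 2730. The 5 others were among 9 regroupings that kept the Foxp3- groups apart and mixed the Foxp3+ groups, which gave 1415 to 2730, a structure set by the Foxp3- groups. Mixing the Foxp3- groups alone gave at most 105, in 11 regroupings, and mixing both gave at most 1, in 79.

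The change from thymus to lymph node differed between Tregs and conventional cells in 1996 genes. The smallest p-values belonged to Cmtm7 (3.44 ± 0.15, adjusted p = 1.04e-13), Klrb1a (5.09 ± 0.24, adjusted p = 3.25e-13) and Ccr10 (6.49 ± 0.32, adjusted p = 7.48e-13). Cmtm7 changed by 0.47 in Tregs and -2.96 in conventional cells, Klrb1a by 0.03 and -5.06, and Ccr10 by 2.51 and -3.97. Against CD24int cells the Klrb1a difference was 0.05 and did not pass. Of 100 regroupings, 1 gave as many genes, the real one at 1996, with the highest other at 1440. Of the 99 others, 85 mixed the conventional groups, gave at most 252 and cannot test chance. The 14 that kept the conventional groups apart gave 951 to 1440, and are too few for a share under 0.05.

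Innate-like transcripts were highest in Foxp3- CD24lo cells, where the planned NK and NKT cell markers had a median excess over Foxp3- CD24hi of 2.70, against 1.16 in precursors (1.94, 1.38 and 0.20 in its arrays), 1.15 in Foxp3- CD24int (1.52, 1.27 and 0.44 in its arrays) and 0.55 in lymph node naive cells. They were not carried by a single array, since over genes at least 8-fold above Foxp3- CD24hi in the mean of the other 2 arrays, the median excess was 4.24, 4.01 and 4.15 in the 3 arrays, 4.01 being the least. Natural killer cells, which a CD4 single-positive sort would remove, stay open, since 6 natural killer genes had a median of 0.39 but Klre1 (2.26), Prf1 (1.23) and Ncr1 (0.65) passed higher, Klra8 (0.12), Cma1 (0.01) and Eomes (-0.20) did not, and only 2 were above the median of all values in Foxp3- CD24hi. Another candidate explanation is innate-like T cells within the gate, whose list had a median of 2.26 with 11 of 11 genes higher and a mean level of 8.79, although 10 of the 11 were above that median in Foxp3- CD24hi thymocytes too and natural killer cells can express some of them. Whether such cells were part of the intended conventional population was not tested.

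Liver transcripts stood out in replicate 3 of Foxp3- CD24hi. Serpina1c (10.35), Ttr (9.84) and Apoa1 (9.35), beside Alb and Hpx, were above all 26 other arrays (2.90 to 3.65, 5.05 to 5.96 and 4.83 to 5.54). A property of the group was argued against, since the other 2 arrays differed from the 24 arrays of other groups by a median of -0.01 over 15 liver genes, and thymic epithelium by a median of 0.05. Liver RNA in that library is a candidate source, with a median of 3.73 (0.16 to 5.40) over the 15 genes against 0.02 for muscle, 0.10 for pancreas, 0.03 for brain, 0.15 for kidney and -0.15 for natural killer genes. Without that array, counts were 5321 for the averaged comparison, 2703 for Foxp3 at CD24hi, 2663 and 626 for Foxp3- CD24lo and CD24int against CD24hi, 1405 for the maturation interaction and 1461 for precursors.

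Precursor arrays held some transcripts of the Foxp3- CD24lo gate. The innate-like T cell list (6 of 11 genes higher, 0 lower) had a median of 0.83, near lymph node naive cells (0.68) and Tregs (0.64). Of 79 genes up at least 8-fold in that gate, 43 were higher in a Treg comparison. Over the 36 others the median excesses over Foxp3- CD24hi were 1.67, 1.65 and 0.38 (1.74, 1.64 and 0.78 over all 79). A single array was argued against by 1.65 in the second highest, a bound first set at 0.5 on the array with the least, which 0.38 would not meet but which cannot tell 1 holding array from 2. Foxp3- CD24lo cells at a fixed share stay open as the whole source. Shares needed by the 36 genes ran from 1.04% (10th percentile) to 14.5% (90th), a ratio of 13.9 (1.54% to 26.1% over all 79). Noise in this ratio was not estimated, and 2 shares were below 0. Klrb1a needed 0.598%, Zbtb16 5.91%, Trgv4 8.93% and Cxcr6 40.2%. The origin stays open, and other populations were not tested.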

How the results depend on the processing

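The replacements of CD24lo by CD24int and the averaged comparison without CD24lo were tests chosen only after the data were seen, and the other alternatives were planned and all were run. Signal over background was not measured, since no detection calls were analysed, and 73.1% of simulated 2-fold changes were recovered in interactions. The largest median log2 difference of all genes in any comparison was 0.042 in size, 0.041 with quantile normalization, 0.03 without dim genes and 0.045 with the mean of all probe sets. Among 298 named gene results, 264 of which passed, 251 kept their direction and call under each alternative run. 1 reversed: Icos in the averaged comparison, at 0.64 without the CD24lo groups. Lists were tested under the 7 settings given next, not with single arrays left out or groups replaced, and no called list had the opposite call there. Erythroid markers were not tested without dim genes, nor was Il2. Lists called numbered 163 of 357, 163 with quantile normalization, 147 of the 340 tested without dim genes, 170 with the mean of all probe sets, 165 with the intensity trend, 171 with the block, 175 with compared groups alone and 83 with an estimated correlation (57 up, 26 down). Without dim genes 17 list calls were lost, with quantile normalization 3, with the mean of all probe sets 2 and with compared groups alone 1. Those not given beside their list were, without dim genes, IL-2 and STAT5 targets for Foxp3+ CD24lo against CD24hi (adjusted p = 0.0675) and mature thymocyte and egress genes (0.0742) for Foxp3+ CD24int against CD24hi. The others were cytokine and helper lineage genes for the maturation difference (0.0979) and precursors (0.121), effector Treg and trafficking genes for Foxp3+ CD24hi against precursors (0.15) and NF-kB and TNF receptor genes for lymph node naive cells (0.0599). With the mean of all probe sets it was apoptosis regulators in lymph node (0.0563).

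Counts of changed genes stayed within 1.5 times under quantile normalization and the intensity trend. A 2-fold minimum gave 730 for the averaged comparison, 755, 821 and 1112 for Foxp3 at CD24hi, CD24int and CD24lo, 732 for lymph node, 156 and 22 for Foxp3+ CD24lo and CD24int against CD24hi and 2 for CD24lo against CD24int. It gave 914, 211 and 606 for the same steps in Foxp3- cells, 780 for their difference, 428 for precursors, 512 for Foxp3+ CD24hi against precursors, 263 and 722 for lymph node Tregs and naive cells against thymus, and 985 for their difference. The minimum itself lowers counts. It turned the excess of lower genes into one of higher genes averaged (440 up, 290 down), at CD24hi (476 up, 279 down), at CD24lo (569 up, 543 down) and for Foxp3- CD24int against CD24hi (113 up, 98 down).

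With the replicate block, counts were 1300, 210 and 23 for the Foxp3+ steps, 1822 and 3407 for Foxp3- CD24int against CD24hi and CD24lo against CD24int, 2490 for their difference, 2671 for precursors, 4443 for Foxp3+ CD24hi against precursors, 1922 for lymph node Tregs against thymus and 3067 for the lymph node difference. The block changed no other named gene call than those given for Cd24a. It ended the call of immature thymocyte genes averaged (adjusted p = 0.0784) and called interferon response genes at CD24int (adjusted p = 0.0454), where numbers did not pair the samples, and dissociation stress genes for Foxp3- CD24lo against CD24int (adjusted p = 0.024). It also called Cd24a at CD24int (0.87, adjusted p = 0.00402) and averaged (0.64, adjusted p = 0.000198), where numbers did not pair the samples. A fit of the compared groups alone, with fewer arrays to estimate the spread, gave 368 for Foxp3+ CD24lo against CD24hi, 552 for Foxp3- CD24int against CD24hi, 1001 for precursors and 1804 for Foxp3+ CD24hi against precursors. In limma it gave 0 for Foxp3+ CD24int against CD24hi (1068 at an unadjusted p under 0.05) and 0 for CD24lo against CD24int (722 at an unadjusted p under 0.05).

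For the following changes the cause was not tested. With the intensity trend Cxcr3 (adjusted p = 0.0658) and S100a4 (adjusted p = 0.0603) did not pass for Foxp3+ CD24int against CD24hi. Cd24a passed in the averaged comparison without dim genes (adjusted p = 0.04) and with compared groups alone (adjusted p = 0.0386). Foxp3+ CD24lo against CD24int gave 9 without dim genes and 10 with the mean of all probe sets. Precursors against Foxp3- CD24int gave 2490. With CD24int in place of CD24lo the maturation difference gave 281, lymph node naive cells 1558 and the lymph node difference 661. The averaged comparison without CD24lo gave 4431. The correlation of Foxp3 effects at CD24hi and CD24int was 0.79 without dim genes, and that of precursor and lymph node effects 0.43, or 0.39 with the mean of all probe sets. Without the 2-fold minimum, a larger signature had, of 1458 genes 425 (29.1%) higher in precursors and 686 (47.1%), 871 (59.7%) and 737 (50.5%) at CD24hi, CD24int and CD24lo, and of 792 lower genes 209 (26.4%) lower in precursors and 394 (49.7%), 423 (53.4%) and 412 (52%) at CD24hi, CD24int and CD24lo.

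Leaving out each array in turn gave 5262 to 5509 for the averaged comparison, 2606 to 3197, 2276 to 2491 and 3258 to 3470 for Foxp3 at CD24hi, CD24int and CD24lo, and 1794 to 1973 in lymph node. Foxp3+ CD24lo against CD24hi gave 346 to 453 (346 and 364 without CD24lo replicates 2 and 3), CD24int against CD24hi 14 to 73 (20 and 14 without CD24int replicates 1 and 2, 25 without CD24hi replicate 3) and CD24lo against CD24int 1 to 7 (1, 7 and 1 without CD24int replicates 1, 2 and 3). The Foxp3- steps gave 2587 to 2780, 626 to 805 and 1706 to 1867, and the maturation difference 1314 to 1471. Precursors gave 1241 to 1551, Foxp3+ CD24hi against precursors 2054 to 3010, lymph node Tregs and naive cells against thymus 748 to 825 and 2069 to 2269, and their difference 1674 to 1877.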

Other observations

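The counts over other splits and the control probe set values were planned, and no test given here was chosen only after the result was seen.

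For each of the 14 comparisons of 3 with 3 arrays, the real split was the 1 of 10 with the most genes, and 10 splits are too few for a share under 0.05. The highest other split gave 1 gene for Foxp3 at CD24hi (3280 in the real split), for Foxp3 at CD24int (2779), for Foxp3+ CD24lo against CD24hi (564), for Foxp3- CD24lo against CD24int (2182) and for precursors (1658), and 3 for Foxp3+ CD24hi against precursors (2917). It gave 0 at CD24lo (3829), between the lymph node groups (2250), for Foxp3- CD24lo (3042) and CD24int (911) against CD24hi, for Foxp3+ CD24int against CD24hi (52) and CD24lo against CD24int (3), and for lymph node Tregs (1078) and naive cells (2658) against thymocytes. For the averaged comparison 1 of 100 regroupings, the real one, gave 5555 genes and the highest other 3503. The others mixed or swapped Foxp3+ and Foxp3- arrays in at least 1 CD24 level, so chance stays untested. Among them, 4 parted as many same-numbered pairs and gave at most 33, and are too few for a share under 0.05. Where the replicate numbers pair the samples, 3 other splits parted as many pairs as the real one and gave at most 1 gene for precursors and 0 in the 12 other comparisons.

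The 3' to 5' difference of the Gapdh control probe sets was highest in replicate 1 of the Foxp3+ groups, at 0.941 for CD24int, 0.49 for CD24hi and 0.461 for CD24lo in log2 units.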
